A study of Mus musculus with 16 samples.

How the data were processed

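RNA of trophoblast from female mouse embryos at embryonic day 7.5 was sequenced from 16 libraries: 3 of wild type (WT), 7 of CAGdelta5, 5 of deltaA and 1 of CAG. Per the labels, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Groups and replicate numbers were taken from the sample titles, and each column of the deposited table was matched to its library by name. The table holds 22654 genes, 947 on the X chromosome, 21707 on autosomes and 0 on the Y chromosome, so a list of Y-linked genes fixed as a check of the labelled sex could not be tested.

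The authors' deposited table gives, per the file headers, an FPKM value (fragments per kilobase of transcript and library size) for each gene and library. Per the submitters' processing notes the genome build was mm9 and the tools included BWA, Cufflinks 2.2.1 and Cuffdiff. Which tool made which value, the annotation and any use of strand are not given in the sources used here. Per the file headers the deposited table also gives a count of allele-specific reads per gene and library, and the percent of these that were paternal. The percent is given from 10 allelic reads upward, and no gene with 9 or fewer has one. How reads were assigned to JF1 or B6, and over which sequence variants, is not given in the sources used here. Group means of FPKM and of the percent are the authors' own, and they equalled the means of the replicates within 0.008 FPKM. The q-value of each mutant group against WT was deposited by the authors per the file headers, and its test is not stated. Coordinates are those of the table on mm9, with 1 added to each start because end minus start equalled the annotated length in 9476 genes and end minus start plus 1 in 617.

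Because FPKM is relative to all fragments of a library, a rise of many genes lowers the others, and RNA of another tissue lowers the genes of the trophoblast. Summed FPKM ran from 475941 to 537836 per library. Allele-specific reads per library ran from 1120520 to 14039339, which sets the precision of shares. Total sequencing depth is not given in the sources used here. Paternal read numbers, taken as the percent times the allelic reads, were whole in 100% of cases (tolerance 1e-06). No pair of libraries had identical values, and the chi-square per degree of freedom between replicates was 10.68 to 110.39, far above sampling noise, so every library counted as a replicate. Reads are not independent molecules, and Wilson intervals (95%) and limits for 0 reads (3 reads of the total) cover counting error only.

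Expression was compared with limma 3.58.1 (lmFit, then eBayes with trend and robust options, R 4.3.3) on log2(FPKM + 1) for 11612 genes with a mean of at least 1 FPKM over the 15 libraries of the 3 replicated groups, in one fit with group as the only factor. P-values were two-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Values are means ± SD over libraries, and SE is the standard error from limma. The CAG library was left out of all fits. For it, medians of gene lists were placed among 10000 random lists of the same size matched on mean expression in 20 bins.

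The paternal share of X-linked expression was, per library, the sum of paternal reads over the sum of allelic reads of X-linked genes without Xist, Tsix, Jpx and Ftx. The autosomal share was the same over autosomal genes outside the imprinted lists. Groups were compared by exact two-sided permutation tests over libraries, whose smallest p is 0.0167 for 3 against 7, 0.0357 for 3 against 5 and 0.00253 for 5 against 7. Changes in paternal share per X-linked gene were tested with limma on log2((paternal + 0.5)/(maternal + 0.5)) for genes with a mean of at least 20 allelic reads, with precision weights from the read numbers and an added variance of 0.1. Allele-specific FPKM of Xist is its FPKM times the allele's share. Shares of single genes are means over libraries with at least 10 allelic reads of the gene.

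Gene lists covered trophoblast stem, ectoplacental cone, giant, chorion and labyrinth, epiblast, endoderm and mesoderm cells, decidua with uterine natural killer cells and maternal blood, imprinted genes by expressed allele, escape genes, the X-inactivation centre, X-linked genes with placental roles, cell cycle, p53 targets, stress response, hypoxia and glycolysis, Polycomb and chromatin, and germline genes. Of 20 lists, 19 had at least 3 tested genes. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated per list. Of the calls at the preset correlation only that of the p53 targets in CAGdelta5 held with the estimated one. Some lists share members, such as Cdkn1a in cell cycle and p53 targets. The groups, main tests, gene lists, naming rule and most alternatives were fixed before the data were examined. By the naming rule the text takes Xist first. Among called genes with a mean of at least 2 FPKM in the higher group and every mutant library on one side of the WT mean, it then takes the 6 largest X-linked rises, 2 X-linked falls, 6 autosomal rises and 6 autosomal falls. From each list it takes up to 4 members with the smallest p, and between the mutants the 5 largest rises and 5 largest falls. For allelic shares it takes the 6 largest rises and the 4 most highly expressed genes not called, and all measured escape and X-inactivation centre genes. Members of counts of 5 or fewer outside the rule were named after their values were seen.

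Alternatives were another pseudocount, other filters, scaling to autosomal genes, fits of only the groups compared, limma without trend and robust options, a fold threshold of 1.5, a replicate block, and each library left out in turn. For shares they were medians, minimum read numbers, lists or top genes left out, and a quasi-binomial model. Chosen after seeing the data were edgeR 4.0.16 quasi-likelihood tests on allelic reads of both alleles, of the paternal and of the maternal allele, the leaving out of CAGdelta5 replicate 2 and deltaA replicate 4 together, the allelic model on imprinted genes and the autosomal median share. The paternal-read test is the one that RNA from maternal tissue cannot enter, except through wrong allele assignment or filled values. Where no percent is given, under 10 allelic reads, the paternal reads had to be filled in. This was so for 2.79% of the values, which may carry maternal reads. For shared controls, pairs of unchanged groups that share 3 controls were simulated 100 times.

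The procedures were tested on simulated data. With 200 of 11612 genes changed, limma recovered 27.5% of 1.5-fold and 75% of 2-fold changes for CAGdelta5 against WT, 18% and 76% for deltaA against WT, and 44% and 85% for deltaA against CAGdelta5, with 2 to 8 false calls. The allelic model recovered 100%, 98.9% and 100% of 4-fold changes over 321, 320 and 345 genes in these 3 comparisons. This does not carry over to genes with very low WT shares. In CAGdelta5 against WT, Tsc22d3 and 1600025M17Rik, both at 0% in WT, had log2 ratio changes of 3.92 (SE 1.87) and 3.42 (SE 2.02). Neither passed (limma adjusted p = 0.0607 and 0.126). Genes that did not pass against WT can thus not be taken as unchanged. The edgeR test recovered 32%, 34% and 54% of 2-fold changes over 10055, 10055 and 10056 genes, so fewer calls on allelic reads may partly reflect lower power. These edgeR rates and those on FPKM are for 200 changed genes, far fewer than were called in the data. The edgeR rates are also for reads of both alleles and not for paternal reads alone. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.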

Results

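The series measured gene expression and its allelic balance in trophoblast of female mouse embryos at embryonic day 7.5 by RNA sequencing. The mothers were of the strain JF1 and the fathers of the strain C57BL/6J (B6), so sequence differences between the strains assigned reads to the maternal (JF1) or the paternal (B6) allele. In mouse trophoblast the paternal X chromosome is normally the silenced one, and Xist, the non-coding RNA that coats and silences it, is transcribed from that chromosome. Groups differed in the paternal Xist allele. There were 3 wild-type libraries (WT), 7 with the allele the labels call CAGdelta5, 5 with the allele called deltaA and 1 with the allele called CAG. By their usual names, deltaA lacks the A repeat that Xist needs for silencing, and a CAG allele is driven by the strong CAG promoter. Reads assigned to an allele numbered 8182406, 14039339 and 2625245 in WT replicates 1 to 3, between 2218454 and 12134270 in CAGdelta5, between 2622302 and 8659867 in deltaA and 1120520 in the CAG library. The single CAG library was given as values without a test. The labels do not say whether replicates came from separate embryos or litters, so the p-values measure the spread between these libraries.

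Xist itself (chromosome X, 100655712 to 100678572, mm9) differed between all 3 replicated groups. Its expression was 58.8 ± 28.6 FPKM in WT (SD, n = 3), 220 ± 59.1 FPKM in CAGdelta5 (n = 7) and 12.4 ± 3.27 FPKM in deltaA (n = 5), and 145 FPKM in the CAG library. On the log2(FPKM + 1) scale it was 1.95 higher in CAGdelta5 than in WT (SE 0.26, adjusted p = 4.35e-05, limma) and it fell by 2.09 in deltaA (SE 0.28, adjusted p = 1.37e-05). The paternal share of Xist reads was 98.7% ± 0.535 in WT, 97.8% ± 1.55 in CAGdelta5, 99.3% in the CAG library and 0.659% ± 0.256 in deltaA. The share in deltaA was below that in WT in every library (exact two-sided permutation p = 0.0357, the smallest for 3 against 5), while the test between CAGdelta5 and WT did not pass (exact permutation p = 0.3). Paternal-allele Xist thus came to 57.9 FPKM in WT, 216 FPKM in CAGdelta5 and 0.076 FPKM in deltaA. Maternal-allele Xist was 0.831 ± 0.734 FPKM in WT (0.41 without WT replicate 3), 4.77 ± 3.34 FPKM in CAGdelta5 and 12.3 ± 3.28 FPKM in deltaA (exact permutation p = 0.0167 and 0.0357 against WT, the smallest each design allows). In CAGdelta5, where the share test did not pass, wrongly assigned paternal reads of the raised Xist could give part of this rise. Tsix, the antisense gene that overlaps Xist and restrains it, had 93.1% ± 7.0 paternal reads in deltaA. Strand use in the counting is not stated, so reads of Xist and Tsix could be exchanged.

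The first question of the design was how far the paternal X was expressed in each group. In WT the paternal X contributed 5.72% ± 0.273 of X-linked allelic reads (n = 3), in CAGdelta5 40.9% ± 1.98 (n = 7) and in deltaA 50.9% ± 1.15 (n = 5), counted without the 4 X-inactivation centre genes Xist, Tsix, Jpx and Ftx. The WT libraries ranged from 5.46% to 6.01%, those of CAGdelta5 from 37.7% to 44.3% and those of deltaA from 49.2% to 51.9%, so no ranges overlapped. The differences were 35.2 points for CAGdelta5 against WT (exact two-sided permutation p = 0.0167), 45.2 points for deltaA against WT (exact p = 0.0357) and 9.99 points for deltaA against CAGdelta5 (exact p = 0.00253). Each of these p-values is the smallest that its group sizes allow. The CAG library, at 6.61% (95% Wilson interval 6.31% to 6.92%, 1706 of 25816 reads), lay above the highest WT library. In the median X-linked gene the paternal share was 0% in WT and in the CAG library, 35.3% ± 3.55 in CAGdelta5 and 49.7% ± 1.74 in deltaA. Intervals from reads cover counting error only.

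**Figure D1:**
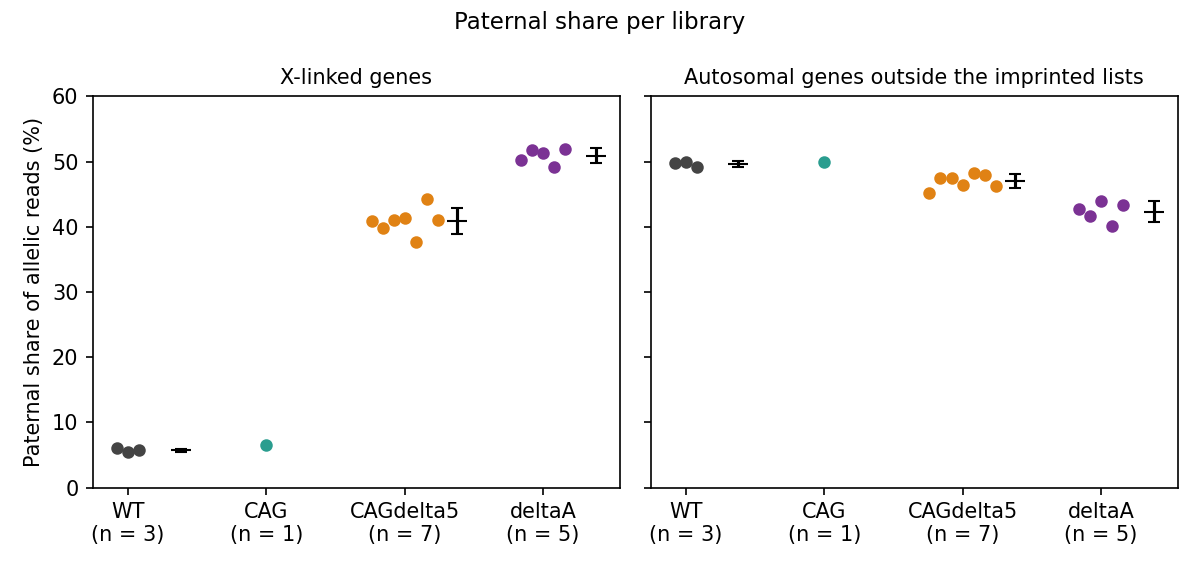
Paternal (B6) share of allelic reads in percent for X-linked genes (left) and autosomal genes outside the imprinted lists (right) by group, with points for libraries and bars for mean ± SD. The X-linked share averaged 5.72% in WT, 40.9% in CAGdelta5 and 50.9% in deltaA, while the autosomal share was 49.6%, 47.0% and 42.4%.

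Gene by gene, the rise in CAGdelta5 was uneven along the chromosome. Of 321 X-linked genes with enough allelic reads in both groups, 259 had a higher paternal share in CAGdelta5 than in WT and the other 62 did not pass (limma on allelic log2 ratios, adjusted p under 0.05). The rises that were largest in points included Trap1a, a tumour antigen gene expressed in trophoblast (chromosome X, 135868222 to 135872704), at 80.8% ± 6.0 against 3.39% ± 1.75 in WT (adjusted p = 2.3e-11). Firre, a long non-coding RNA gene (47908921 to 47988435), reached 66.0% ± 9.69 against 2.62%, and Il2rg, the common cytokine receptor chain (98459726 to 98463545), 54.8% ± 1.63 against 0.13%. Drp2, Praf2 and Kcnd1 rose to 62.3%, 56.7% and 55.0%, from 1.32%, 0.20% and 0% in WT, the last from 0 of 110 reads, which allows a share of up to 2.73%. The 4 with the highest mean FPKM among those that did not pass were 1600025M17Rik at 16.9% ± 12.1, Tsc22d3, a glucocorticoid-induced regulator, at 7.16% ± 5.71 (adjusted p = 0.0607), Xist, and Ogt, the O-GlcNAc transferase, at 43.7% against 39.5% in WT (adjusted p = 0.12). By mean share, 81 of 345 genes in CAGdelta5 lay under 10% paternal, 83 between 10% and 35%, and 181 at 35% or more. In WT 298 of 321 lay under 10%, and in deltaA 309 of 344 lay at 35% or more. These class limits were chosen after the shares were seen, as were the list members named below beyond the naming rule, where a count was 5 or fewer.

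In deltaA most X-linked genes had a higher paternal share than in WT. Of 320 genes measured against WT, 311 had a higher paternal share, 1 had a lower share, which was Xist, and 8 did not pass. Firre reached 86.7% ± 2.81, Trap1a 83.6% ± 2.28, Fndc3c1 79.2% ± 20.04, Drp2 77.5%, Mum1l1 76.6% and Sms, spermine synthase, 74.95%. Of the 8 that did not pass, the 4 with the highest mean FPKM were Ogt (44.6%), Dynlt3 (87.3% against 75.6% in WT), Mid1 (78.6% against 85.1%) and AW822252 (6.60% against 2.83%). Compared directly, 188 of 345 genes had a higher paternal share in deltaA than in CAGdelta5 and 5 a lower one. Eda, the ectodysplasin gene, stood at 69.0% ± 13.3 in deltaA against 2.17% ± 3.21 in CAGdelta5 (adjusted p = 2.72e-05). Tro, encoding the adhesion protein trophinin, was at 68.8% against 2.22%, Prrg3 at 64.7% against 0.62%, and Eif1ax, a translation initiation factor, at 70.6% against 6.61%. Armcx4 rose from 3.65% to 70.2%, and Trpc5os from 0 of 196 reads, which allows up to 1.53%, to 63.3%. Other genes had close shares in both mutants: Plac1, which the placenta needs for its growth, had 51.0% and 50.7% paternal reads, Rhox9 50.8% and 50.2%, Rhox6 48.4% and 48.0%, and Tmsb4x 40.7% and 38.9%, with none of the 4 passing.

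**Figure D2:**
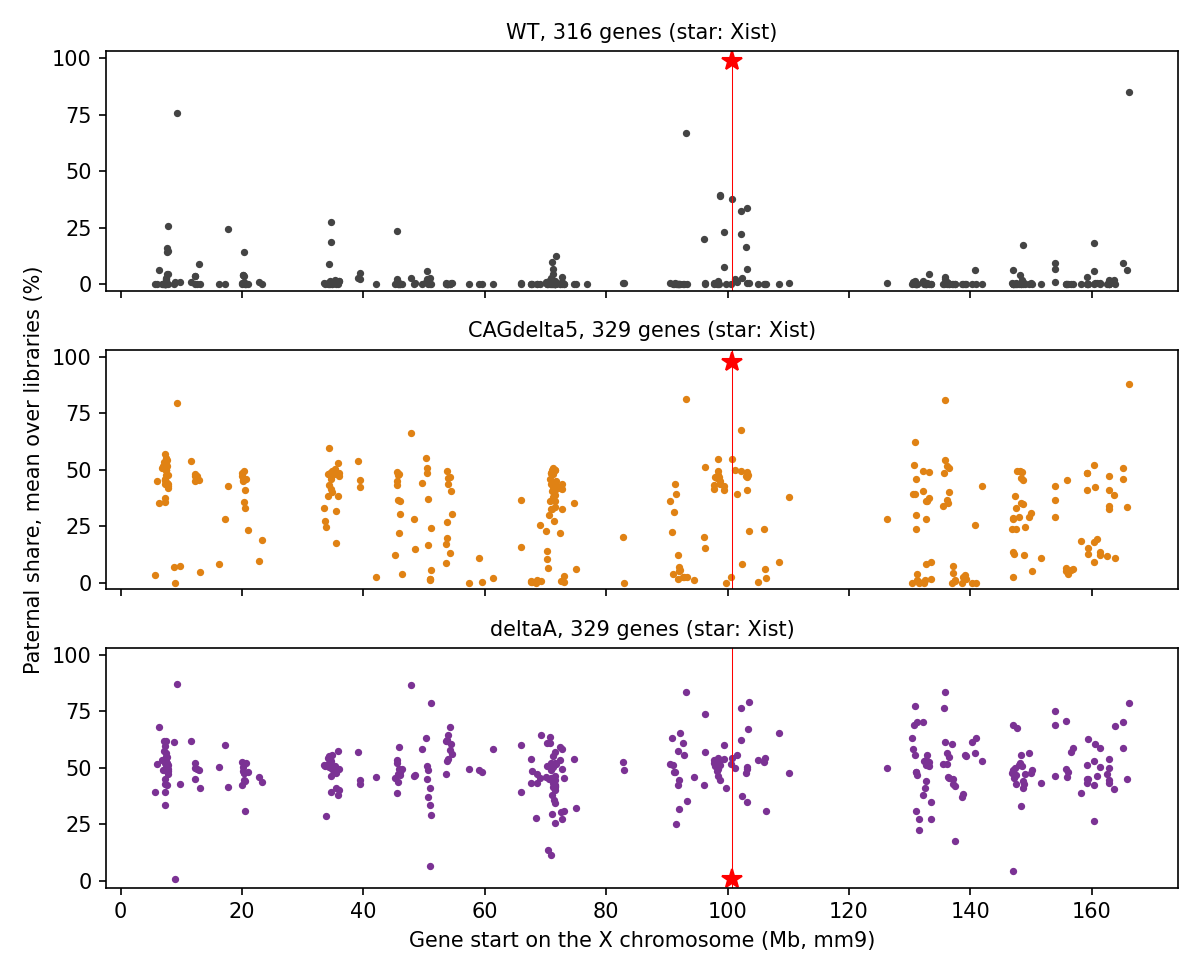
Mean paternal share in percent of each X-linked gene against its position on chromosome X in Mb (mm9) for WT (316 genes), CAGdelta5 (329 genes) and deltaA (329 genes), with Xist marked. WT genes lie mostly near 0%, deltaA genes around 50%, and CAGdelta5 genes spread between those levels, with stretches of low share next to stretches near 50%.

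Several genes known to escape X inactivation were partly paternal already in WT. The WT share was 24.2% ± 7.15 for the histone demethylase Kdm6a, 17.3% ± 2.83 for Kdm5c, 8.85% for Ddx3x, 14.2% for Uba1, 23.8% for Utp14a, 22.3% for Pbdc1 and 32.3% ± 17.0 for 5530601H04Rik. In CAGdelta5 these became 42.6%, 45.4%, 45.4%, 46.0%, 43.1%, 67.4% and 49.3%, and in deltaA 41.7%, 44.3%, 49.1%, 47.9%, 52.0%, 76.7% and 62.3%, and all 7 passed in both mutants. Shroom4, 1810030O07Rik and Syap1 had 0.26%, 3.66% and 3.34% in WT and rose to 44.8%, 47.3% and 40.8% in CAGdelta5 and 51.6%, 45.0% and 43.4% in deltaA. Mid1, 85.1% ± 8.61 paternal in WT, was at 87.9% and 78.6% and did not pass in either mutant. Car5b, at 6.06%, 8.86% and 26.5% in WT, CAGdelta5 and deltaA, passed only in the test between the mutants (adjusted p = 0.00218), as did Bgn, at 36.0% in CAGdelta5 and 61.0% in deltaA (adjusted p = 0.0289) with too few reads in WT. Around the X-inactivation centre, Rlim, the ubiquitin ligase that activates Xist, rose from 2.26% to 49.7% in CAGdelta5 and 49.9% in deltaA, and Ftx, a non-coding RNA gene next to Xist, from 37.9% to 54.6% and 54.2%. Chic1 was at 2.31% in CAGdelta5 against 0 of 70 reads in WT, which allows up to 4.29% (adjusted p = 0.422), and reached 51.6% ± 19.5 in deltaA (adjusted p = 0.00402). Slc16a2 was at 2.63%, 2.27% and 17.9% and passed between the mutants (adjusted p = 0.00813) but not against WT. Jpx had 67.1% ± 35.6, 48.3% ± 27.9 and 42.2% ± 28.4 over 2, 4 and 4 libraries, on reads too few for the test.

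Autosomal genes gave the background for these shares. Their summed paternal share was 49.6% ± 0.448 in WT, 47.0% ± 1.09 in CAGdelta5 and 42.4% ± 1.54 in deltaA, and 49.9% in the CAG library (95% Wilson interval 49.85% to 50.04%). The share dropped by 2.61 points in CAGdelta5 (exact two-sided permutation p = 0.0167) and by 7.28 points in deltaA (exact p = 0.0357), and it was lower in deltaA than in CAGdelta5 (exact p = 0.00253). Markers of the maternal tissue around the embryo did not pass as a list in either mutant by camera, which compares a list with all other genes. With fry of limma, which tests each list by itself, the list had unadjusted p = 0.00453 in CAGdelta5 and 0.00145 in deltaA. Of 19 measured genes of decidua, uterine natural killer cells and maternal blood, 7 rose in CAGdelta5 and 12 did not pass, whether tested over all genes or adjusted over the list alone (camera adjusted p = 0.239). In deltaA 10 rose and 2 fell, as many as when adjusted over the list alone (camera adjusted p = 0.365). Prl8a2, a prolactin-family hormone of decidual cells, went from 106 ± 105 FPKM in WT to 475 ± 180 in CAGdelta5 (log2 fold change 2.51, adjusted p = 0.000584) and 1860 ± 712 in deltaA (4.49, adjusted p = 3.55e-06), with 0.0733% ± 0.0510 paternal reads in deltaA. Its WT mean was 45.0 FPKM without WT replicate 3. Cryab, a small heat shock protein gene, rose by 1.97 and 2.64 and had 12.6% and 9.67% paternal reads, and Hoxa10 rose by 1.10 and 1.82. Igfbp4 rose by 2.30 and 1.75, with 32.7% paternal reads in deltaA and 53.7% in WT. The genes that fell in deltaA were Col3a1 and Hba-a1, by 1.81 and 1.37. Gzmc to Gzmg, Prf1 and Hba-a1, markers of natural killer cells and blood, had a median log2 fold change of -1.79 in deltaA, and the decidual genes Prl8a2, Cryab, Hoxa10, Hoxa11 and Des one of 1.82, in sets chosen after the values were seen. Between the mutants, 6 members were higher and 1, Col3a1, lower in deltaA, again as many adjusted over the list alone (camera adjusted p = 0.575, for higher, with a median log2 difference of -0.21).

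Expression in CAGdelta5 differed from WT across the genome. Among 11612 genes tested, 3003 rose and 1855 fell (limma on log2(FPKM + 1), adjusted p under 0.05), with 203 of 426 X-linked genes rising and 21 falling. The largest X-linked rises were in the Rhox homeobox cluster, which is expressed in reproductive and extraembryonic tissues. Rhox9 (chromosome X, 35252274 to 35254947) went from 53.8 ± 11.2 FPKM in WT to 1376 ± 501 in CAGdelta5 (log2 fold change 4.60, SE 0.25, adjusted p = 1.09e-08), Rhox6 from 143 ± 33.2 to 2179 ± 735 (3.88) and Rhox12 from 0.205 to 21.5 ± 11.3 (4.07). Rhox6 and Rhox9 are near-identical copies that can share reads, and on allelic reads alone the rise of Rhox6 missed the threshold (2.39, edgeR adjusted p = 0.0561). Arhgef6, an exchange factor for Rho-family GTPases, 1600025M17Rik and 1700013H16Rik rose by 2.91, 3.12 and 3.22. The 2 largest X-linked falls were Alas2, the heme synthesis enzyme of red cells, by 1.39 (adjusted p = 0.00207), and the dyskerin gene Dkc1, by 1.31 (adjusted p = 0.000508).

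On autosomes, the largest rises in CAGdelta5 included genes of the p53 response. Of 19 measured p53 targets, 17 rose and 2 did not pass, and the same counts held adjusted over the list alone (camera adjusted p = 3.4e-08, and adjusted p = 0.021 with an estimated correlation). Cdkn1a, the p21 inhibitor of the cell cycle (chromosome 17, 29227931 to 29237667), went from 6.56 ± 1.19 to 67.2 ± 11.99 FPKM (log2 fold change 3.17, SE 0.16, adjusted p = 4.75e-09) with 39.8% paternal reads. Phlda3, an inhibitor of Akt, rose from 3.40 to 47.8 ± 8.55 FPKM (3.48), and the cell death regulators Trp53inp1 and Bbc3 by 2.44 and 2.58. Among 25 measured cell cycle genes 3 rose and 11 fell, or 4 and 13 adjusted over the list alone (camera adjusted p = 0.0107, and adjusted p = 0.566 with an estimated correlation). The 3 that rose, Cdkn1a, Cdkn1b and Cdkn1c, encode inhibitors of cyclin-dependent kinases. Cyclin E1 (Ccne1) fell by 1.09, the replication helicase gene Mcm5 by 0.60 and the ribonucleotide reductase gene Rrm2 by 0.65. Maternal tissue can supply paternal reads only through wrong allele assignment or filled values. On paternal reads alone 12 of 15 autosomal p53 targets were higher, and of 20 cell cycle genes 2 were higher and 7 lower (edgeR, adjusted p under 0.05). Other large autosomal rises were Krt14, a basal keratin (11.4 ± 13.1 to 111 ± 54.5 FPKM, 3.81), Cldn4, a tight junction gene (3.21, adjusted p = 1.65e-08), Cryba4 (3.16) and Dio3, which inactivates thyroid hormone (0.078 to 20.5 ± 25.6 FPKM, 3.54). Without CAGdelta5 replicate 5 the mean of Dio3 was 11.4 FPKM and its log2 fold change 3.10, and without WT replicate 1 the WT mean of Krt14 was 4.11 FPKM and its log2 fold change 4.76. The largest falls were Hpdl (20.4 ± 6.55 to 3.18 ± 1.17 FPKM, -2.36), Tmem59l (-1.96), Gm6793 (-1.90), Pear1 (-1.74), Adm, encoding the vasodilator peptide adrenomedullin (4374 ± 218 to 1469 ± 590 FPKM, -1.71), and the kinase gene Lck (-1.70). Without WT replicate 1 or 2 the call of Gm6793 was lost (adjusted p = 0.0584 and 0.0565), and Pear1 was not lower in maternal reads (0.08).

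Over all genes and libraries, no cell type list passed by camera in CAGdelta5. Of 19 giant cell genes 9 rose and 1, Adm, fell (as many adjusted over the list alone, camera adjusted p = 0.156), with Bhlhe40, a transcription factor, rising by 1.57. Of 16 genes of chorion and labyrinth progenitors 9 rose and 7 did not pass, or 10 and 6 adjusted over the list alone, among them Epcam (36.2 ± 1.91 to 94.3 ± 16.0 FPKM, 1.34), an adhesion molecule of epithelial progenitors, Ovol2 (1.79) and Pparg (1.47). Their camera adjusted p of 0.0551 went to 0.0458 with X-linked genes left out, to 0.015 without CAGdelta5 replicate 2 and to 0.0467 without WT replicate 2. Of 20 endoderm genes 6 rose, Gata4 (1.49) and Gata6 (1.78) among them, and 1, Thbd, fell, as many adjusted over the list alone (camera adjusted p = 0.122, but 0.0457 without CAGdelta5 replicate 6 and 0.0263 without WT replicate 3). Of 13 trophoblast stem genes Eomes and Bmp4 rose and Tfap2c fell (camera adjusted p = 0.895), of 12 ectoplacental cone genes Flt1, Prdm1, Tpbpb and Ppp2r2c rose and Prl5a1 fell (0.815), of 7 mesoderm and blood genes Runx1, Hand2 and Vim rose (0.857), and each count was the same adjusted over the list alone. Dnmt3b, the de novo methyltransferase, was the only one of 7 epiblast genes to pass, with a fall of 0.91, and it did not pass adjusted over the list alone (camera adjusted p = 0.895). Leaving out WT replicate 1 ended the calls of Eomes, Bmp4, Tfap2c, Flt1, Prdm1, Tpbpb, Hand2 and Dnmt3b (adjusted p from 0.0545 to 0.24). Without WT replicate 2 those of Eomes, Bmp4, Tfap2c, Prdm1, Tpbpb, Hand2, Vim, Dnmt3b and Prl5a1 were lost (0.0737 to 0.281), and without WT replicate 3 those of Vim, Dnmt3b and Prl5a1 (0.0605 to 0.107). The log2 fold change of Bmp4 (0.90) was 0.45 without WT replicate 1 and 1.36 without WT replicate 3, and that of Vim (1.23) was 0.64 without WT replicate 2. Single CAGdelta5 libraries also decided Dnmt3b (replicates 1, 2, 3, 6 and 7), Vim (1, 6 and 7) and Tpbpb (4, 5 and 7), with adjusted p from 0.0509 to 0.0782. With all libraries, Vim was also lost after scaling to autosomal genes (1.14, adjusted p = 0.055), Vim and Dnmt3b without the filter on low values (0.0583 and 0.0757), and Vim, Bmp4, Prdm1, Tpbpb and Hand2 with only the groups compared in the fit (0.0539 to 0.0732). On allelic reads Eomes, Tfap2c, Prdm1 and Vim missed the threshold (0.98, -0.21, 0.79 and 1.12, edgeR adjusted p = 0.0619, 0.58, 0.0653 and 0.0769), as did Prl5a1 on paternal reads (-0.79, edgeR adjusted p = 0.074). Tpbpb had 0 paternal reads of 2911 in CAGdelta5, which allows a share of up to 0.103%.

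In CAGdelta5 X-linked genes with placental roles counted 10 rising and 2 falling of 22, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.0291, adjusted p = 0.566 with an estimated correlation, and 0.0515 without WT replicate 1). Nrk, a kinase that limits placental growth, rose from 48.2 ± 9.83 to 219 ± 85.0 FPKM (2.09), Tmsb4x by 1.79, while Sms and Pdha1 fell by 0.92 and 0.74. Of 15 escape genes Shroom4 (1.49), Bgn (2.37), Syap1 (0.77), 1810030O07Rik (0.52), Mid1 (1.22) and Kdm5c (0.49) rose, Eif2s3x (-0.88) and Utp14a (-0.60) fell, and the other 7 did not pass, in both adjustments, the second adjusted over the list alone (camera adjusted p = 0.262). On allelic reads Eif2s3x had a log2 fold change of -1.38 and missed the threshold (edgeR adjusted p = 0.591). Of 4 X-inactivation centre genes Xist and Rlim (0.74) rose, with Ftx (-0.01) and Slc16a2 (0.41) not passing, in both adjustments, the second adjusted over the list alone (camera adjusted p = 0.223). Stress response genes rose in 6 and fell in 4 of 17 cases, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.895). Atf3 (1.37) and Sesn2 (1.66) were among the former and the serine, asparagine and amino acid transport genes Psat1, Phgdh, Asns and Slc7a5 the latter. Phgdh, -1.09 in FPKM, was at 7.82 on paternal and 7.83 on maternal reads, where it did not pass (edgeR adjusted p = 0.105 and 0.098). Of 22 hypoxia and glycolysis genes 3 rose (Vegfa, Hk1 and Ndrg1) and 5 fell (Adm, Eno1, Pkm, Hk2 and Pfkl), or 3 and 4 adjusted over the list alone (camera adjusted p = 0.239). Pkm was lost without WT replicate 2 (adjusted p = 0.0553) and missed the threshold on allelic reads (-0.59, edgeR adjusted p = 0.116), and Vegfa, at 0.89 in FPKM, missed it on paternal reads (0.41, edgeR adjusted p = 0.231). Of 31 Polycomb and chromatin genes 6 rose, including Ezh1 (0.77), and 4 fell (Uhrf1 by 0.71, Hnrnpk, Hnrnpu and Dnmt3b), or 5 and 2 adjusted over the list alone (camera adjusted p = 0.706), and Hnrnpk was lost without WT replicate 3 (adjusted p = 0.0548). On paternal reads Hnrnpk and Hnrnpu missed the threshold (-0.24 and 0.12, edgeR adjusted p = 0.312 and 0.83). Rpl10l, a testis-type ribosomal gene, rose by 1.89 as 1 of 4 germline genes, also adjusted over the list alone (camera adjusted p = 0.288).

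More genes differed between deltaA and WT. Among the 11612 tested, 3614 rose and 2615 fell, with 305 of 426 X-linked genes rising and 14 falling (limma, adjusted p under 0.05). Rhox9 reached 1391 ± 270 FPKM (log2 fold change 4.67, SE 0.27, adjusted p = 9.44e-09) and Rhox12 65.4 ± 18.6 FPKM (5.74). 1600025M17Rik went from 9.33 ± 0.777 to 339 ± 111 FPKM (4.98), 4933402E13Rik from 1.95 (1.22 without WT replicate 3) to 87.5 ± 12.4 (4.98), Arhgef6 from 6.47 to 153 ± 25.5 (4.42) and Gm648 from 1.27 to 46.9 ± 6.63 (4.39). Apart from Xist, the largest X-linked fall was Bcor, a transcriptional corepressor, from 104 ± 10.1 to 44.9 ± 13.6 FPKM (-1.25, adjusted p = 0.00205). Of 22 X-linked genes with placental roles 12 rose, including Nrk (2.73), Tmsb4x (2.61) and Rhox6 (3.89), and Sms and Bcor fell, as many adjusted over the list alone (camera adjusted p = 0.0128, and adjusted p = 0.356 with an estimated correlation). Of 15 escape genes Shroom4 (1.95), Syap1 (1.19), Bgn (2.37), Car5b (1.69), 1810030O07Rik (0.48) and Kdm5c (0.41) rose, and Eif2s3x fell by 0.85, as many adjusted over the list alone (camera adjusted p = 0.379). On allelic reads Eif2s3x was not lower (0.80, edgeR adjusted p = 0.74). In the X-inactivation centre list Rlim (1.02) and Slc16a2 (1.06) rose, Xist fell and Ftx (-0.13) did not pass, the same adjusted over the list alone (camera adjusted p = 0.943), and Slc16a2 missed the threshold on allelic reads (edgeR adjusted p = 0.0508).

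In deltaA the lists of p53 targets, cell cycle genes and hypoxia and glycolysis genes passed with camera's preset correlation, and none of the 3 with an estimated one. Of 19 p53 targets 16 rose, 1 fell and 2 did not pass, as many adjusted over the list alone (camera adjusted p = 4.98e-05, and adjusted p = 0.115 with an estimated correlation). Cdkn1a stood at 55.5 ± 7.72 FPKM (log2 fold change 2.90, SE 0.17, adjusted p = 9.44e-09), Trp53inp1 rose by 3.29 and the X-linked receptor gene Eda2r by 2.89, while Bax, which promotes cell death, fell by 0.60. Phlda3 rose by 3.17 in FPKM and missed the threshold on allelic reads (2.23, edgeR adjusted p = 0.304). Among 25 cell cycle genes Cdkn1a, Cdkn1b and Ccnd2 rose and 16 fell, or 3 and 17 adjusted over the list alone (camera adjusted p = 0.000183, and adjusted p = 0.375 with an estimated correlation). Mcm5 fell by 0.91, the mitotic kinase gene Aurka by 1.44 (78.5 ± 4.89 to 28.7 ± 5.32 FPKM) and Rrm2 by 1.04. Of 22 hypoxia and glycolysis genes 4 rose (Vegfa, Pfkp, P4ha1 and Hk1) and 11 fell, as many adjusted over the list alone (camera adjusted p = 0.0214, adjusted p = 0.803 with an estimated correlation, and 0.0503 without WT replicate 2). The enolase gene Eno1 fell by 1.70, Pfkl by 1.67, Pkm by 1.19 and hexokinase 2 (Hk2) by 1.86. The rise of Vegfa, 1.14 in FPKM, was absent from paternal reads (0.04, edgeR adjusted p = 0.92, against 1.45 on maternal reads), and its paternal share was 39.9% in WT and 15.8% in deltaA. On paternal reads alone 12 of 15 p53 targets were higher, 14 of 20 cell cycle genes lower and 2 higher, and 8 of 18 hypoxia and glycolysis genes lower and 3 higher (edgeR, adjusted p under 0.05). Of the 19 markers of decidua, natural killer cells and blood given above, 10 rose and 2 fell in the same libraries (camera adjusted p = 0.365).

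**Figure D3:**
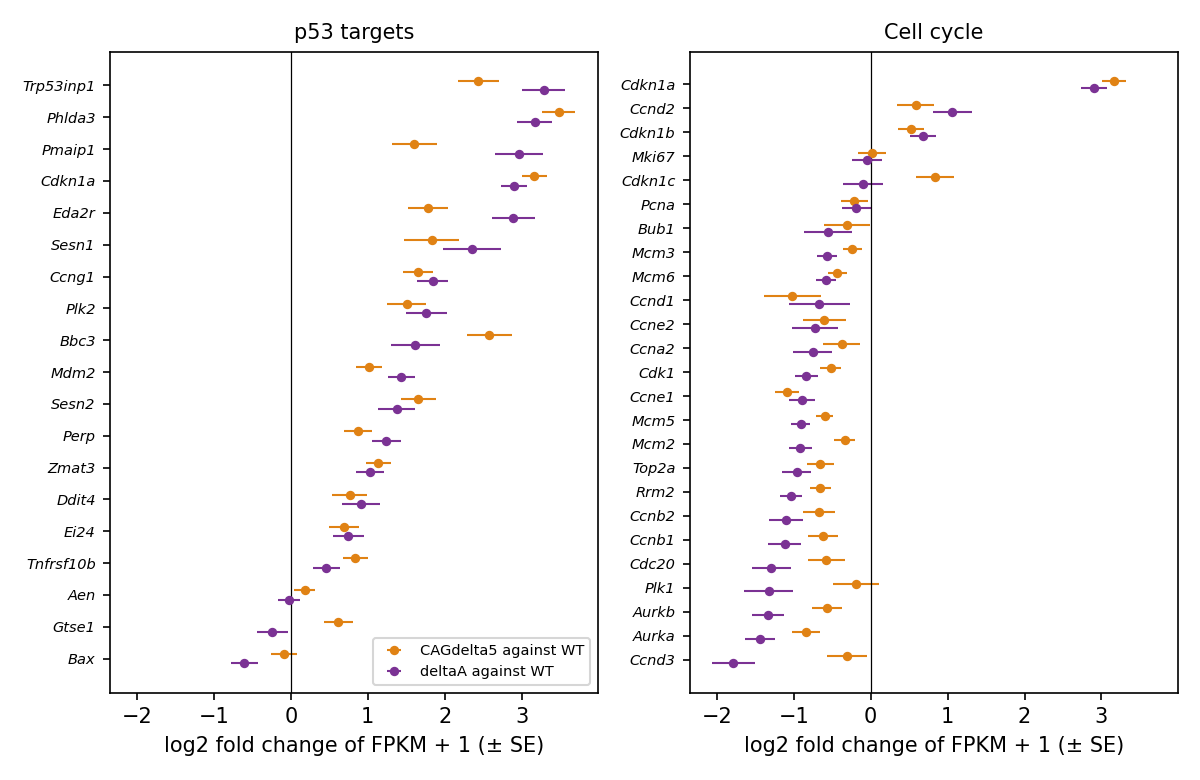
Log2 fold change against WT (± SE, on the log2(FPKM + 1) scale) of each measured p53 target and cell cycle gene in CAGdelta5 (orange) and deltaA (purple). Cdkn1a stands at 3.17 and 2.90, and most cell cycle genes lie below 0 in both mutants, with lower values in deltaA.

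Large autosomal changes in deltaA included genes read almost only from the maternal allele. Prl8a9, a prolactin-family gene, went from 258 ± 186 to 6220 ± 2354 FPKM (log2 fold change 4.73, adjusted p = 6.02e-07) with 0.354% ± 0.146 paternal reads, and the trophoblast gene Tpbpb from 10.4 ± 13.5 to 213 ± 134 FPKM (4.70, adjusted p = 0.0016) with 0.234% paternal reads. Without WT replicate 3 their WT means were 151 and 2.62 FPKM. Such low shares were not particular to deltaA: Tpbpb had 0 of 262 paternal reads in WT, which allows up to 1.15%, and Prl8a9 0.386% in the CAG library. Prolactin-family members are close copies that can share reads. Rsad2, an interferon-induced antiviral gene, rose by 4.58, Krt14 by 4.66 and Cldn4 by 4.09, to 186 ± 27.0 FPKM. The largest falls were Ceacam9 (408 ± 184 to 43.0 ± 32.6 FPKM, -3.41), the imprinted growth regulator Phlda2 (820 ± 383 to 82.5 ± 21.5 FPKM, -3.23), Hpdl (-3.09), Isyna1, which makes inositol (-2.57), Hmga1-rs1 (-2.48) and Ascl2, a transcription factor that spongiotrophoblast needs (83.6 ± 28.0 to 15.9 ± 7.91 FPKM, -2.42). Of 12 ectoplacental cone genes Flt1, Prdm1, Tpbpb and Prl7b1 rose and Phlda2, Ascl2 and Gjb3 fell (camera adjusted p = 0.714). Of 13 trophoblast stem genes Eomes (1.80) and Bmp4 rose and Tfap2c (-1.06), Wnt7b, Ets2 and Cdx2 fell (camera adjusted p = 0.545). Both lists kept these counts adjusted over the list alone. Bmp4 (1.08) was lost without WT replicate 1 (0.64, adjusted p = 0.0961), while Tfap2c was not called on allelic reads (edgeR adjusted p = 0.159), nor Wnt7b, Ets2 and Cdx2 on paternal reads (edgeR adjusted p = 0.181, 0.285 and 0.585), and the rise of Prdm1 was absent there (-0.10). Of 19 giant cell genes 11 rose, including Rhox9, Rhox6, Bhlhe40 (2.07) and Serpinb9b (1.76), and 6 fell, among them Adm (-1.87), as many adjusted over the list alone (camera adjusted p = 0.374). Another of the 11, Prl6a1 (3.79), was lower on paternal reads (-4.18, edgeR adjusted p = 0.000518) and had 0.0713% paternal reads.

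With all libraries, none of the remaining lists passed by camera in deltaA. Of 16 chorion and labyrinth genes 6 rose, including Epcam (1.87), Fzd5 (1.48) and Ovol2 (1.79), and Slc16a1 and Slc16a3, both lactate transporters, fell (camera adjusted p = 0.379). Of 7 epiblast genes Pou5f1, Nanog and Otx2 rose and Utf1 (-1.78) and Dnmt3b (-0.90) fell (camera adjusted p = 0.71). Pou5f1 and Otx2 were listed at 0 in all 3 WT libraries and averaged 16.7 ± 14.8 and 2.70 ± 3.48 FPKM in deltaA, or 10.5 and 1.18 FPKM without deltaA replicate 5. Of 20 endoderm genes Gata4 and Gata6 rose and Thbd fell by 1.32 (camera adjusted p = 0.943), and without WT replicate 2 both rises were lost (adjusted p = 0.0596 and 0.0903). Of 7 mesoderm and blood genes Runx1 (1.46), Hand2 and Vim rose (camera adjusted p = 0.545), Vim (1.46) missing the threshold without WT replicate 2 (0.88, adjusted p = 0.131). On allelic reads Gata6 and Vim missed the threshold (0.71 and 1.03, edgeR adjusted p = 0.32 and 0.0987). Each of these 4 lists kept its counts adjusted over the list alone. Stress response genes rose in 6 and fell in 4 of 17 cases, as many adjusted over the list alone (camera adjusted p = 0.943), with Atf3 up by 1.75 and Slc7a5, Psat1, Asns and Phgdh down, the last with -1.84 in FPKM but 8.71 on allelic reads, where it did not pass (edgeR adjusted p = 0.0895). Of 31 Polycomb and chromatin genes Ezh1 (0.96), Jarid2, Pcgf5 and Bmi1 rose and 7 fell, led by Uhrf1 (-1.49), Cbx2 (-1.03) and Dnmt3l (-2.01), or 2 and 5 adjusted over the list alone (camera adjusted p = 0.254), and Jarid2 missed the threshold on paternal reads (0.12, edgeR adjusted p = 0.646). All 4 germline genes, Rpl10l (1.91), Asz1 (1.18), Tex101 (0.96) and Ddx4 (0.62), rose, also adjusted over the list alone (camera adjusted p = 0.0941), and Ddx4 was lost without WT replicate 1 or 2 (adjusted p = 0.0576 and 0.0715).

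Directly compared, the mutants differed at 3208 genes. In deltaA 1587 genes were higher and 1621 lower than in CAGdelta5, with 194 X-linked genes higher and 15 lower. Xist was lower by a log2 difference of -4.04 (SE 0.22, adjusted p = 2.06e-08). Taf7l, a germ cell transcription factor gene on the X (130994655 to 131011029), went from 2.10 ± 1.40 to 17.9 ± 4.76 FPKM (2.69, adjusted p = 1.91e-05), Magea5 from 0.655 to 7.14 ± 1.66 (2.33), 4933402E13Rik by 2.38, Gm648 by 2.33 and Prl8a9 by 2.38. The largest falls besides Xist were Scand1 (25.3 ± 24.4 to 1.98 ± 2.48 FPKM, -2.87, adjusted p = 0.011), Phlda2 (-2.56), Dio3 (-2.39) and Ascl2 (-2.20). Without deltaA replicate 1 the mean of Scand1 there was 0.892 FPKM. Of 25 cell cycle genes 11 were lower, among them Aurka (-0.59), Rrm2 (-0.38) and Mcm5 (-0.31), and 14 did not pass, or 12 and 13 adjusted over the list alone (camera adjusted p = 0.00151, and adjusted p = 0.679 with an estimated correlation). Hypoxia and glycolysis genes were lower in 10 of 22 cases, including Pfkl (-1.11) and Eno1 (-0.74), or 11 adjusted over the list alone (camera adjusted p = 0.00438, and adjusted p = 0.679 with an estimated correlation). Of 20 endoderm genes only Thbd passed, with a fall of 0.56, and it did not pass adjusted over the list alone, while the list as a whole was lower (median log2 difference -0.81, camera adjusted p = 0.00888, adjusted p = 0.679 with an estimated correlation, and 0.0506 without deltaA replicate 4). On allelic reads of both alleles edgeR called 1928 genes between the mutants. On paternal reads 4 of 20 cell cycle genes and 4 of 18 hypoxia and glycolysis genes were lower (edgeR, adjusted p under 0.05).

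No other list passed between the mutants. Eomes was higher and Tfap2c, Cdx2, Wnt7b and Ets2 lower among 13 trophoblast stem genes (camera adjusted p = 0.201). Phlda2, Ppp2r2c, Ascl2, Gjb3 and Pcdh12 were lower among 12 ectoplacental cone genes (0.402), and Nanog, Pou5f1 and Otx2 were higher and Utf1 lower among 7 epiblast genes (0.352). Each of these counts was the same adjusted over the list alone. Giant cell genes had 3 higher (Prl6a1, Serpinb9b and Prl3d1) and 4 lower members (Mdfi, Gata2, Hand1 and Gata3) of 19, or 7 and 4 adjusted over the list alone (0.973). Prl6a1, 2.03 in FPKM, was higher on maternal reads (1.84, edgeR adjusted p = 0.013) and lower on paternal reads (-2.69, edgeR adjusted p = 0.0294). Chorion and labyrinth genes had 4 higher (Met, Epcam, Fzd5 and Lifr) and 7 lower of 16, as many adjusted over the list alone (0.551). Pecam1 was higher among 7 mesoderm genes but not adjusted over the list alone (0.401). Of 19 p53 targets Pmaip1, Eda2r, Trp53inp1 and Mdm2 were higher and Gtse1, Bbc3 and Bax lower, or 4 and 4 adjusted over the list alone (0.973). Trib3, Slc7a5 and Phgdh were lower among 17 stress response genes, as many adjusted over the list alone (0.551). On paternal reads Mdm2 (-0.004), Trib3 (0.05) and Phgdh (0.35) were not called (edgeR adjusted p = 0.99, 0.933 and 0.91). Of 31 Polycomb and chromatin genes Hdac3 was higher and 7, led by Uhrf1 (-0.78), lower, or 1 and 6 adjusted over the list alone (0.0733). That list passed without deltaA replicate 2 or 5 (adjusted p = 0.0242 and 0.0307) and without CAGdelta5 replicate 2 or 7 (0.0355 and 0.0359). Escape genes had Car5b, Shroom4 and Syap1 higher and Mid1 and Uba1 lower of 15 (0.551), and the X-inactivation centre list Slc16a2 higher and Xist lower of 4 (0.575), as many adjusted over the list alone in both. Placental X-linked genes had 6 higher, among them Pdha1 (1.08), and Bcor and Pgk1 lower of 22 (0.201), while Asz1, Ddx4 and Tex101 were higher of 4 germline genes (0.104), as many adjusted over the list alone in both.

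The X as a whole was raised relative to autosomes in both mutants. The median log2 fold change of X-linked genes was 0.50 in CAGdelta5 and 0.97 in deltaA, against 0.07 and 0.05 for autosomal genes. Per library, the X-linked median minus the autosomal median was 0.006 ± 0.080 in WT (n = 3), 0.423 ± 0.050 in CAGdelta5 (n = 7), 0.887 ± 0.091 in deltaA (n = 5) and 0.099 in the CAG library. CAGdelta5 exceeded WT by 0.42 (exact two-sided permutation p = 0.0167), deltaA exceeded WT by 0.88 (exact p = 0.0357) and deltaA exceeded CAGdelta5 by 0.46 (exact p = 0.00253), each the smallest p the group sizes allow. X-linked genes were more often called higher than autosomal genes, with odds ratios of 2.73 (95% interval 2.23 to 3.33, Fisher's exact p = 6.61e-23) in CAGdelta5, 6.0 (4.83 to 7.5, exact p = 2.17e-68) in deltaA and 5.88 (4.79 to 7.20, exact p = 3.95e-60) in deltaA against CAGdelta5. Camera on all X-linked genes other than Xist gave p = 0.0263, 0.00235 and 0.00362 with an estimated correlation, by limma. X-linked genes took 3.0% to 3.45% of summed FPKM in WT, 5.22% to 6.47% in CAGdelta5, 6.37% to 7.55% in deltaA and 3.49% in the CAG library. The maternal X allele, measured against autosomal maternal alleles, was at -0.14 ± 0.06 in CAGdelta5 and -0.15 ± 0.08 in deltaA against 0.01 ± 0.11 in WT (exact permutation p = 0.05 and 0.0714). Without that reference its median against the WT mean was -0.065 ± 0.087 in CAGdelta5 and -0.003 ± 0.07 in deltaA. Autosomal maternal alleles lay at 0.024 to 0.148 in the CAGdelta5 libraries and 0.105 to 0.18 in those of deltaA. The deltaA value thus reflects higher autosomal maternal alleles rather than a lower maternal X.

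**Figure D4:**
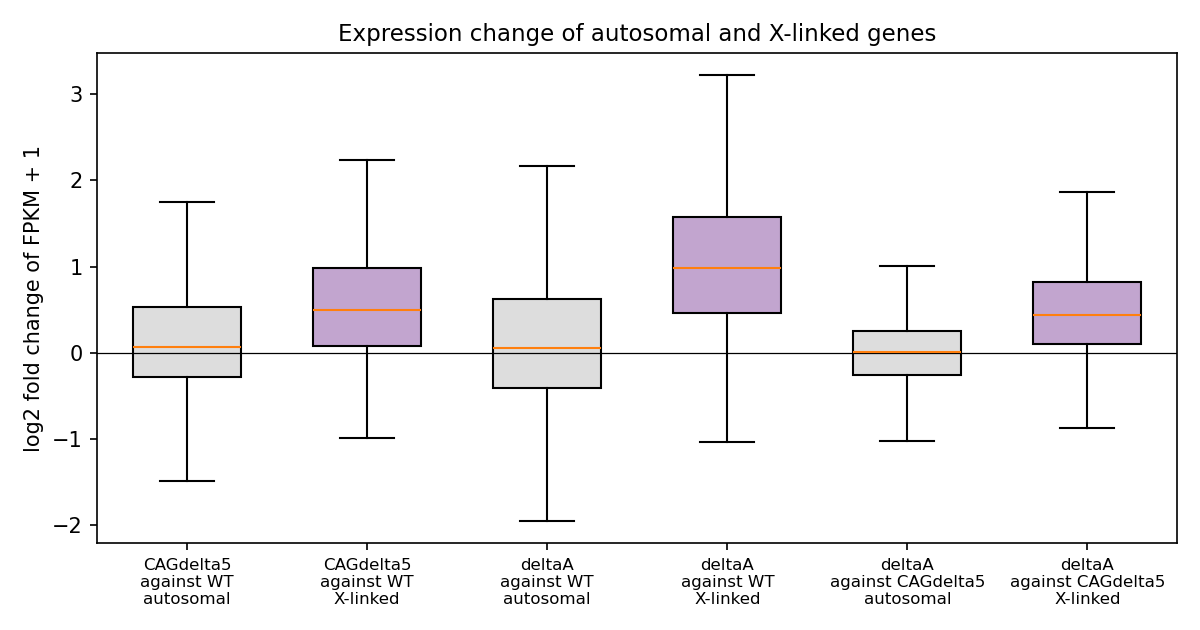
Log2 fold changes (on the log2(FPKM + 1) scale) of X-linked genes without Xist and of autosomal genes in the 3 comparisons, as boxes from the lower to the upper quartile with the median line and whiskers to 1.5 times the interquartile range. The X-linked medians lie at 0.501, 0.979 and 0.435, and the autosomal medians near 0.

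Some imprinted genes changed in level or in allelic share, while with all libraries neither imprinted list passed by camera in any comparison of levels. Of 19 measured genes expressed from the maternal allele 9 rose and 1, Nap1l4, fell in CAGdelta5, or 10 and 1 adjusted over the list alone (camera adjusted p = 0.109, but 0.0347 without CAGdelta5 replicate 2). In deltaA 8 rose and Phlda2, Ascl2 and Nap1l4 fell, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.704). Of 18 genes expressed from the paternal allele 9 rose and Sfmbt2 fell by 0.72 in CAGdelta5 (camera adjusted p = 0.239), and 8 rose and Sfmbt2 fell by 0.90 in deltaA (0.439), as many adjusted over the list alone. Meg3, a maternally expressed non-coding RNA gene of the Dlk1 domain, rose by 1.67 and 1.51. Ndn, of the paternally expressed list, rose by 1.85 and 1.46, the latter missing the threshold on allelic reads (1.25 in deltaA, edgeR adjusted p = 0.0586). Its paternal share was 32.2% in CAGdelta5 and 39.0% in deltaA. The lists name the allele usually expressed, and not all members followed it here. In WT the paternal share was 55.35% for Ube3a and 40.1% for Igf2r, both listed as maternally expressed. It was 39.0% for Inpp5f, listed as paternally expressed. Between the mutants Ampd3 and Tfpi2 were higher and Cd81, Phlda2, Ascl2, Cdkn1c and Tssc4 lower in deltaA, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.277). Of the paternally expressed genes Impact and Mest were higher and Peg12 and Smoc1 lower, also adjusted over the list alone (0.915). The paternal share of Meg3 reads went from 3.59% ± 0.98 in WT to 28.4% ± 11.5 in CAGdelta5 (adjusted p = 9.66e-05) and 43.3% ± 4.65 in deltaA (adjusted p = 5.5e-06), and that of its neighbour Mirg from 3.82% to 32.6% and 41.5%. Tfpi2 went from 18.1% to 39.3% and 45.8%. Jade1, paternally expressed, went from 85.2% to 67.5% and 60.1%, and Gab1 from 94.8% to 84.1% and 79.3%, whereas Peg3 was at 99.7%, 99.8% and 99.5% without passing. Over the lists, 8 of 20 maternally expressed genes had a higher paternal share in CAGdelta5 and Ampd3 a lower one, and 6 had a higher and 2 a lower share in deltaA (Ampd3 and Osbpl5). Of 14 paternally expressed genes Smoc1, Jade1 and Gab1 had a lower share in CAGdelta5, and 8 a lower and 1, Igf2, a higher share in deltaA. Impact alone passed between the mutants, at 68.8% in CAGdelta5 and 45.7% in deltaA (adjusted p = 0.000194). The per-library median over maternally expressed genes was 8.41% ± 2.18, 24.2% ± 5.38 and 21.3% ± 7.17 in WT, CAGdelta5 and deltaA (exact permutation p = 0.0167 and 0.0714 against WT), and over paternally expressed genes 95.3% ± 1.32, 90.4% ± 4.68 and 90.8% ± 2.15 (exact p = 0.0333 and 0.0357). The autosomal paternal share also fell in both mutants. For paternally expressed genes with lower shares, maternal RNA and a change of imprinting therefore cannot be told apart.

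Many changes were shared by both mutants. Of the 11612 genes, 2456 rose in both and 1530 fell in both, and 4 moved in opposite directions. Both comparisons use the same 3 WT libraries. With no effect, 100 simulated pairs of unchanged groups that shared 3 controls gave 0 shared calls. Few genes pass at all without an effect, so this does not measure how much of the overlap the WT libraries create. Independent lists of these lengths would share 935 rises and 418 falls. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.851 against a simulated mean of 0.651 (highest 0.878), and the covariance 0.494 against 0.04 (highest 0.097), a difference of 0.454. With 3 controls no split leaves 2 in each part, so some of the excess may come from the shared controls. In the authors' deposited table, 4603 genes had a q-value under 0.05 in CAGdelta5 (3245 higher and 1358 lower), 5808 in deltaA (3728 and 2080) and 161 in CAG (109 and 52). Of the limma calls, 77.7% in CAGdelta5 (3777 of 4858) and 79.7% in deltaA (4966 of 6229) also passed in the authors' deposited table, all in the same direction. Of autosomal limma calls that could be tested on paternal reads, 60.8% (2275 of 3739) in CAGdelta5, 62.2% (2917 of 4690) in deltaA and 26.7% (617 of 2307) between the mutants were called there in the same direction (edgeR, adjusted p under 0.05).

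The single CAG library resembled WT more than either mutant group in number of genes away from the WT mean. It had 140 genes at least 2-fold from the WT mean of FPKM + 1, against 1075 to 2312 in the CAGdelta5 libraries and 2430 to 3114 in the deltaA libraries. Cdkn1a stood at 6.55 FPKM (6.56 in WT), Rhox9 at 52.9 FPKM (53.8) and Prl8a2 at 91.5 FPKM (106), and 78 of 121 named genes lay within the range of the WT libraries. Its X-linked median log2 fold change of 0.10 lay at percentile 100 of 10000 random lists matched on expression, and within the WT libraries' range of -0.07 to 0.12. Placental X-linked genes (median 0.15, percentile 99.8), chorion and labyrinth genes (0.22, 98.9) and paternally expressed imprinted genes (0.18, 98.7) lay above the ranges of the WT libraries, which ended at 0.06, 0.06 and 0.08. Endoderm genes (0.90, percentile 100) lay within the WT range of -0.71 to 1.14, as did decidual markers (-0.19, percentile 0.3, WT -0.39 to 0.59). Cell cycle genes were at -0.05 (percentile 50.2) and p53 targets at 0.08 (percentile 88.4, WT -0.12 to 0.03). The median paternal share was 2.97% over maternally expressed and 96.5% over paternally expressed imprinted genes.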

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

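The rule for single libraries standing apart was set in advance, while the tests of other splits of the samples were chosen only after the counts were seen. A library was listed where its gap to the nearest library of its group was a large part of the group's range (Dixon's test at 95%, groups of 5 and 7). Chance lists about 1 in 20 groups, or 12.9 of the 258 groups of values tested, and 31 were listed, 24 in CAGdelta5 and 7 in deltaA. In CAGdelta5, replicates 1, 2 and 5 held 6, 8 and 6 of them. Values are FPKM unless given as percent, and the range of the other libraries of the group stands beside each.

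CAGdelta5 replicate 2 was highest for the endoderm genes Gata4 at 77.4 (24.4 to 44.2), Gata6 at 49.6 (11.6 to 22.8) and Pth1r at 257 (50.2 to 94.0), and for Vim, of the mesoderm and blood list, at 274 (52.1 to 105). It was also highest for Tmem59l at 4.62 (1.16 to 2.42), Peg13 at 3.77 (1.63 to 2.16) and Sesn2 at 49.7 (28.7 to 36.4), and lowest for Tfap2c at 159 (206 to 235). CAGdelta5 replicate 1 was highest for the epiblast genes Pou5f1 at 19.5 (0 to 1.93), Nanog at 2.17 (0 to 0.393) and Otx2 at 1.69 (0 to 0.136), and for Syap1 at 31.0 (18.7 to 22.0), Rlim at 199 (99.8 to 129) and Asz1 at 2.05 (0.572 to 1.06). CAGdelta5 replicate 5 was highest for Dio3 at 75.2 (0.906 to 27.1), Cldn4 at 147 (80.8 to 107), Hand2 at 5.33 (0.564 to 1.33), Phlda2 at 1620 (182 to 715), Gata1 at 14.6 (1.45 to 6.19) and Hoxa10 at 5.09 (0.845 to 1.94).

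Single values stood apart in the remaining libraries. CAGdelta5 replicate 3 was highest for Rsad2 at 52.7 (10.6 to 19.7), replicate 4 lowest for Shroom4 at 16.0 (19.3 to 21.3), replicate 6 lowest for Rpl10l at 10.2 (15.7 to 19.8) and replicate 7 highest for Atf3 at 14.6 (4.2 to 6.91). In deltaA, replicate 1 was highest for Bbc3 at 10.8 (3.32 to 5.02) and Scand1 at 6.34 (0.312 to 1.52). DeltaA replicate 4 was lowest for Slc7a5 at 13.7 (29.3 to 35.6) and for the median paternal share of X-linked genes at 46.6%, with the other libraries up to 51.0%. DeltaA replicate 5 was highest for Otx2 at 8.79 (0.129 to 2.14) and Gm648 at 58.7 (42.9 to 44.4) and lowest for Phlda2 at 45.0 (84.4 to 97.9).

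Other splits of the same libraries into groups of the same sizes were fitted in the same way. Where more than 100 splits were possible, 100 were fitted, the real one and others drawn at random. For CAGdelta5 against WT, 1 of 100 splits, the real one, gave as many genes (4858, highest other split 363), X-linked genes (224 against 8) and X-linked genes with a changed paternal share (259 against 3). For deltaA against WT, 1 of 56 splits, the real one, gave as many (6229 against 932, 319 against 40 and 312 against 1). For deltaA against CAGdelta5, 1 of 100 splits gave as many (3208 against 1800, 209 against 138 and 193 against 159). Among the splits fitted, the real one thus gave the largest value for all 9 counts, which are not independent of each other. Splits that were not drawn, in the 2 comparisons with 100, could have given more. With these numbers of splits the smallest possible fraction is 1 in 56 or 1 in 100. Differences of litter, pool or batch that run with the groups cannot be seen in such splits.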

How the results depend on the processing

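The edgeR tests on allelic, paternal and maternal reads and the leaving out of CAGdelta5 replicate 2 and deltaA replicate 4 together were chosen only after the results were seen. Of 524 values that answer a comparison under an alternative, 435 held their side of the threshold, 69 kept their direction and lost the threshold, and 20 counts or values moved. Those that held include values that were not called and changed direction. The paternally expressed imprinted genes between the mutants did so with single libraries left out. Of 4254 values of single genes and lists, 4077 held, 136 lost and 27 gained the threshold, 8 moved and 6 reversed. Scaling to autosomal genes moved the median of all genes by -0.08, -0.09 and -0.01 in the 3 comparisons and the share of calls that were higher from 61.8% to 52.4% in CAGdelta5 and from 58% to 51% in deltaA.

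The 6 reversals, all of genes taken by the naming rule, were in edgeR tests on allelic reads and did not pass there: Eif2s3x in deltaA at 0.80 (adjusted p = 0.74) and Phgdh in deltaA at 8.71 (0.0895) on both alleles, Prdm1 in deltaA at -0.10 and Phgdh at 8.16 on paternal reads, and Pear1 in CAGdelta5 at 0.077 and Phgdh at 7.32 on maternal reads. Over all autosomal calls, 1 in CAGdelta5, 10 in deltaA and 2 between the mutants passed in the opposite direction on paternal reads, Prl6a1 in deltaA (-4.18) and between the mutants (-2.69) among them. The cause was not tested. With a pseudocount of 0.1 the log2 fold changes of low genes were larger, such as 5.99 for Dio3 in CAGdelta5 and 6.94 for Pou5f1 in deltaA. Counts between the mutants moved most: 1770 genes at 1.5-fold or more, 129 X-linked genes at 5 FPKM or more, where fewer (295) were tested, 1928 genes and 122 X-linked genes on allelic reads, 1551 on maternal reads and 761 on paternal reads. On paternal reads 2544 genes were called in CAGdelta5 and 3269 in deltaA, of 9186 autosomal genes tested, with fewer genes and lower power by construction. With an estimated correlation 1 list passed in CAGdelta5, 0 in deltaA and 0 between the mutants, against 3, 4 and 3 with camera's preset one. At unadjusted p under 0.05 the estimated correlation gave 1, 2 and 0 lists, and fry, which tests each list by itself, gave 12, 12 and 5 at adjusted p under 0.05. Without CAGdelta5 replicate 2 and deltaA replicate 4 together 6 lists passed in CAGdelta5. A list's median, mean and camera direction differed in sign only where no call was made: in CAGdelta5 for epiblast, stress response and Polycomb genes, in deltaA for ectoplacental cone, X-inactivation centre and stress response genes, and between the mutants for ectoplacental cone, decidua, paternally expressed imprinted, X-inactivation centre, p53 and stress response genes. The CAG library's X-linked paternal share was 5.40% without the escape list and 6.95% without Nrk, Plac1, Rlim, Ldoc1 and Uba1, the 5 X-linked genes with most reads.

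With each library left out in turn, directions held except for the paternally expressed imprinted genes between the mutants, which were not called and lay on both sides of 0. The smallest p that the smaller designs allow, 0.0556 for 2 against 7 and 0.0571 or 0.0952 for deltaA against WT, ended the permutation calls by construction. The paternally expressed list in CAGdelta5 also reached an exact p of 0.111. The ranges for CAGdelta5 against WT, deltaA against WT and deltaA against CAGdelta5 were as follows. X-linked share differences were 34.6 to 35.7, 44.9 to 45.6 and 9.46 to 10.6 points, and autosomal ones -2.87 to -2.32, -7.70 to -6.71 and -5.09 to -4.10 points. Maternally expressed imprinted genes ran from 14.6 to 17.1, 10.9 to 15.7 and -4.90 to -0.104 points, and paternally expressed ones from -5.59 to -3.63, -5.18 to -3.65 and -0.895 to 1.28 points. The Xist share ran from -1.26 to -0.48, -98.4 to -97.8 and -97.6 to -96.9 points. The X-linked minus autosomal median ran from 0.39 to 0.46, 0.85 to 0.93 and 0.45 to 0.50. Genes called numbered 3381 to 4939, 4979 to 6212 and 2189 to 3769, X-linked genes 176 to 227, 283 to 320 and 170 to 216, X-linked genes with a changed paternal share 227 to 262, 288 to 313 and 186 to 195, and lists 2 to 5 (5 without CAGdelta5 replicate 2), 3 to 4 and 2 to 4.

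The labels give the groups the same replicate numbers, but these did not pair the libraries: correlations of same-numbered deviations ran from -0.346 to 0.51, with 0.51 for replicate 1 of deltaA and WT. With the replicate block and only shared numbers, 2536 genes and 134 X-linked genes were called in CAGdelta5, 727 and 94 between the mutants, and 2457 in both mutants. Paired differences were 34.9, 45.4 and 10.7 points for the X-linked share, -2.89, -6.84 and -4.63 for the autosomal share, 16.4 for maternally expressed genes in CAGdelta5, -6.29 and -4.16 for paternally expressed genes in CAGdelta5 and deltaA, -98.1 and -96.8 for the Xist share of deltaA against WT and CAGdelta5, and 0.44, 0.85 and 0.46 for the X-linked median. Exact tests over 3 or 5 pairs cannot go below 0.25 or 0.0625. Depth limits shares most where reads are few, since no percent is given under 10 allelic reads.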

Other observations

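The tests in this part were chosen only after the results they bear on were seen, except for the scaling to autosomal genes, which was planned as an alternative. Some X-linked genes stayed mostly maternal in CAGdelta5. Of 81 genes under 10% paternal there, a limit chosen after the shares were seen, with 83 more between 10% and 35%, 71 were under 20% in every library with a value. The 8 with the highest mean FPKM, picked after the values were seen, were Hmgn5, a nucleosome-binding protein gene (0.05% in WT, 6.03% ± 5.67 in CAGdelta5 and 54.5% ± 1.98 in deltaA), 3830417A13Rik (0.19%, 1.88% and 58.4%), Pdha1 of pyruvate dehydrogenase (0.26%, 5.70% and 56.9%), Klhl13 (0.93%, 9.48% and 45.8%), the membrane linker gene Msn (0.01%, 2.30% and 35.4%), Tsc22d3 (0 of 322 reads, 7.16% and 42.7%), Zfp36l3 (0 of 76 reads, 5.67% and 29.2%) and Xlr3a (0 of 313 reads, 6.42% and 13.7%). Counts of 0 allow up to 0.932%, 3.95% and 0.958%. The median log2 fold change in CAGdelta5 was 0.28 for tested genes under 10% and 0.73 for those at 35% or more.

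Neither tested technical explanation accounts for these low shares as a group. If too few reads made them, genes under 10% in 6 of the libraries would lie under 20% in the library left out about as often as all genes, which did so in 28.6% to 34.9% of cases, and they did so in 88.3% to 98.7%. Maternal RNA in proportion to the fall of the autosomal share would lower these shares more in deltaA, where the autosomal share was 42.4% against 47.0%, and their median there was 45.9% against 51.3% for genes at 35% or more in CAGdelta5. Whether the fall of the autosomal share measures maternal RNA was not settled, so other maternal RNA stays open. A candidate explanation is silencing by the CAGdelta5 Xist RNA that persisted at these genes, a hypothesis from the same data that no further sample tests.

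The lower autosomal paternal share of the mutants, a fall of 5.26% ± 2.2 of the WT mean in CAGdelta5 and 14.7% ± 3.11 in deltaA, was weighed for 4 sources. Depth would shift the deltaA share by -0.24 points against the -7.28 seen, and an allele assignment that lowers every gene alike would lower the cell cycle genes, whose median change was -0.88 points against -4.78 over all autosomal genes (random lists -8.84 to -1.14). Uterine natural killer cells or maternal blood would raise their genes, and Gzmc to Gzmg, Prf1 and Hba-a1 had a median log2 fold change of -1.79 in deltaA. Of these only Hba-a1 was called lower, and single libraries moved the means in both groups. Gzmd, for example, was at 27.3 FPKM in WT (12.7 without WT replicate 3) and 23.3 FPKM in deltaA (6.75 without deltaA replicate 5). This source is therefore not excluded. Maternal decidual stroma may contribute, since Prl8a2, Cryab, Hoxa10, Hoxa11 and Des rose by a median of 1.82. These 5, under 20% paternal, were picked after their shares were seen, the list they come from did not pass as a whole by camera, and Cryab and Des are not limited to decidua.

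Whether such maternal tissue could bring the autosomal changes themselves was tested on paternal reads. Maternal tissue adds to these only through wrong allele assignment or filled values (Prl8a9, at 0.354% paternal in deltaA, passed there with 5.65, edgeR adjusted p = 9.04e-06). Of the calls testable there, 60.8% in CAGdelta5 and 62.2% in deltaA also passed in the same direction on paternal reads, or 61.2% (2225 of 3634) and 63.1% (2795 of 4430) of those on genes with at least 20% paternal reads in the mutant, which argues against maternal tissue as the whole cause in those comparisons. Between the mutants 26.7% did (617 of 2307, with 2 passing in the opposite direction). On maternal reads 49.6% (1210 of 2441) were kept there, a wider gap than against WT, where 69.6% in CAGdelta5 and 75.4% in deltaA were kept. The wider gap goes with a part from maternal tissue, and the calls kept on paternal reads go with a difference between the mutations. For the calls not kept these sources cannot be told apart, because the test also has lower power on fewer reads. A shift of the FPKM scale by the X-linked rise is argued against, since 94.0% of autosomal calls in deltaA passed again after scaling to autosomal genes. A smaller part of the changes may still come from maternal tissue, and an effect of the Xist mutations on these genes, directly or through X-linked dosage, remains untested.

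Shares in CAGdelta5 varied along the chromosome and with expression, in 8 relations computed across genes, which are not independent replicates. Adjacent genes had similar shares (Spearman rho 0.46 over 344 pairs, upper bound of the middle 95% of shuffled orders 0.101, p = 0.0001, the smallest the shuffles allow, adjusted p = 0.00016). The share was higher for genes with higher mean FPKM (rho 0.41, 345 genes, p = 1e-05, the smallest allowed, adjusted p = 2e-05), but a higher share itself adds to FPKM, so this may be in part circular. With distance from Xist the share had a rho of 0.25 (345 genes, p = 1e-05, adjusted p = 2e-05) that rested on the first 40 Mb, since without them it was -0.017 (261 genes, p = 0.78, adjusted p = 0.78). Before Xist rho was 0.35 (220 genes, p = 1e-05, adjusted p = 2e-05) and after it 0.029 (125 genes, p = 0.75, adjusted p = 0.78). The rise in share went with the log2 fold change in CAGdelta5 (rho 0.39, 325 genes, adjusted p = 2e-05) and did not pass in deltaA (rho 0.11, p = 0.055, adjusted p = 0.074). In bins of 20 Mb the median share in CAGdelta5 was 47.2% and 45.3% in the first 40 Mb, 22.3% from 80 to 100 Mb, and 30.7%, 28.9%, 28.3% and, in a last bin of 18 genes, 33.6% in the bins from 100 Mb on.

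Maternal-allele Xist rose in both mutants, and one hypothesis was that embryonic cells of deltaA transcribe it beyond the maternal RNA in the libraries. Per percent fall of the autosomal share, maternal-allele Xist was 0.888 ± 0.38 FPKM in CAGdelta5 and 0.863 ± 0.25 FPKM in deltaA, a difference of -0.0256 (exact two-sided permutation p = 0.866). In CAGdelta5 total Xist rose while its paternal share did not pass against WT (97.8% against 98.7%, exact permutation p = 0.3). Wrongly assigned paternal reads could thus give part of the maternal-allele value in CAGdelta5. The value per percent fall decides neither way, since the source of the reads in either group was not measured. Maternal tissue and the embryo cannot be told apart for Xist.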
